A study of Drosophila melanogaster with 4 samples.

How the data were processed

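Expression was measured in whole final-instar larvae of Drosophila melanogaster with Affymetrix arrays, 1 array for each of 4 groups (control 3 h, infected 3 h, control 6 h, infected 6 h). Per the labels' protocols, total RNA was amplified by 1 round of in vitro transcription and biotin-labelled. The deposited values are signal intensity per probe set on a linear scale, from 0.3 to 43034.5. The values themselves show that the authors scaled the arrays to 1 level, since the mean of the signals after trimming 2% at each end was 500.02 in every array; the software and the method of summarising probes are not given in the sources used here, nor are detection calls used here. The median signals were 65.6, 74.5, 78.1 and 78.8 in the order above. Nothing states how many larvae were pooled per array. The p-values rest on the spread between these 4 arrays pooled across probe sets, which may be technical in part. No pair of arrays held more than 63 identical values of 18769, Affymetrix controls left out.

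The table held 18952 probe sets, of which 183 are Affymetrix controls and were left out of all tests. Of the other 18769, 13646 had 1 gene symbol in the platform annotation, 402 several, and 4721 are unnamed here; none was named from several symbols. Symbols were looked up by gene identifier in a RefSeq gene table of the Release 6 assembly, used for names only, and 0 needed updating. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. Probe sets of near-identical family members, such as the Bomanins, can share signal, which was not tested.

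From the deposited intensity, log2(signal + 16) was taken and each array was centred on its median over all non-control probe sets, because the medians differed by more than 0.1 log2. This shifted the arrays by 0.14, -0.01, -0.06 and -0.07. Probe sets with a mean level at or above the median were kept (9385), and for gene lists 1 probe set per gene, the one with the highest mean level, stood for the gene (7807 genes). Centring moved the median of the kept probe sets to -0.13 for infected against control at 3 h, 0.04 at 6 h and -0.21 for the controls at 6 h against 3 h; as deposited these medians were 0.02, 0.05 and -0.01. Gene lists were read relative to this shift, through their percentile.

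Infection over both times was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on the 4 arrays with infection and time as terms and Benjamini-Hochberg adjustment, calling an adjusted p under 0.05. This leaves 1 residual degree of freedom, which is the difference between the responses at the 2 times, and a difference in response between times is therefore not tested. Differences at a single time compare 1 array with 1 array and have no p-value; a 2-fold difference was counted. The 34 gene lists, the design and the rule for named genes were fixed before the data were examined. For each list with 2 or more measured genes, the median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A gene is called measured where a probe set with 1 symbol passed the level filter. The filter uses the mean of all 4 arrays, so a gene low in 1 array can pass through the others. The Turandot and the larval serum and fat body protein lists had 0 measured genes. Their 5 and 3 genes named on the array lay below the filter, so these lists were not assessed. Of the dosage compensation list msl-2 alone was measured (-0.34 at 3 h and 0.67 at 6 h). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

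Named genes were the 10 highest and 10 lowest differences at each time, 10 genes each way with the largest smaller difference of both times, up to 4 measured members of each list by mean difference, 8 genes each way between the controls, 5 each way by difference between responses and up to 10 each way past limma. Genes outside this rule that complete a count of 5 or fewer, or that were singled out, were chosen after their values were seen: CecB, AttD, Drsl4, IM33, TwdlB, TwdlM, Srg1, Idgf1 and Listericin. The test of infection was checked on simulated data with 200 changed probe sets among 9385: 87% of 2-fold and 100% of 4-fold changes were recovered, with 13 unchanged probe sets among 200 calls. The simulation drew independent normal noise by level, left out the largest spreads and gave each change the same size at both times. These rates therefore need not hold for the real arrays, where responses differed between times. For lists at 6 h, a shift of 0.5 planted in 15 of 7807 genes fell outside the central 95% in 100% of 200 draws, and unshifted lists in 4.5%. The unshifted lists were random genes, so their rate was set in advance and need not hold for lists whose genes vary together. Several lists also lay outside the central 95% between the uninfected arrays, as given below. Each infection difference uses 1 of those arrays, so a list's percentile at 3 h or 6 h can carry a difference between the uninfected samples.

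Alternatives fixed beforehand were quantile normalization, the values as deposited, no filter and a filter at the 75th percentile, pseudocounts of 1 and 64, eBayes without a trend or robust, no covariate, fold thresholds of 1.5 and 3, the mean of a gene's probe sets, and leaving out each array. Centring on the median of the filtered probe sets was added after the data were seen. RNA quality was read from the control probe sets. The ratio of 3' to 5' signal was 1.64 to 2.14 for GAPDH, 1.99 to 2.85 for the actin control, 3.58 to 4.45 for eIF-4a and 2.63 to 4.24 for Act5C over the 4 arrays. It was highest in infected 3 h for each of these transcripts, by little for GAPDH, which had 2.12 to 2.14 in every array but control 3 h.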

Results

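Transcript levels were measured in whole final-instar larvae of Drosophila melanogaster, of a yellow white stock, after exposure to Ganaspis xanthopoda, a parasitic wasp that lays its eggs inside fly larvae. Per the labels, larvae spent 3 h or 6 h with wasps, the presence of a wasp egg was checked, and controls were handled in parallel without wasps. Each of the 4 combinations of infection state and time was hybridized to 1 Affymetrix array, so no value at a single time has a replicate, and the number of arrays limits the precision of every value. The number of larvae behind each array is not given in the sources used here. The median deposited signal was 65.6 in control 3 h, 74.5 in infected 3 h, 78.1 in control 6 h and 78.8 in infected 6 h. Across the 9385 probe sets kept for analysis, Pearson's correlation of log2 signal between arrays ran from 0.967 to 0.982, across probe sets, which are not independent replicates. All differences below are log2, infected minus control unless stated, and folds are on the log2(signal + 16) scale, which understates the change of dim probe sets.

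The first comparison asked which transcripts differed between infected and control larvae over both times. Genes of the humoral immune response were among those that rose. Mtk, which encodes the antifungal peptide Metchnikowin, rose by 3.16 ± 0.25 (limma SE, 2 infected and 2 control arrays), an 8.97-fold difference, with 2.35 at 3 h and 3.98 at 6 h (limma adjusted p = 2.6e-09). Each ± here is this SE, which limma pools across probe sets, so it does not show the spread of a gene's own arrays. BomS2, BomBc2, BomS5, BomT2 and BomS6, which encode short secreted Bomanin peptides induced by the Toll pathway, rose by 3.37, 3.08, 2.94, 2.85 and 2.84. The control 3 h signals of BomBc2 and BomT2, and of BomBc3 below, were 3.5, 4.4 and 6.2. These lie under the pseudocount of 16, so differences of single arrays that use control 3 h are lower bounds for these genes. Their means over both times are fitted averages and not bounds. Over the other settings those means fell to 2.23 for BomBc2, 1.84 for BomT2 and 0.85 for BomBc3. The genes that fell included Alp9 and Alp10, which encode alkaline phosphatases, and Pepck1, a gluconeogenic enzyme, at -1.47, -1.09 and -1.22.

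Of the 7 measured antimicrobial peptide genes, out of 13 named on the array, 5 rose, and the same 5 passed when adjusted over the list alone. Drs, which encodes the antifungal peptide Drosomycin, rose by 2.64 ± 0.26, DptB, a diptericin, by 1.83 ± 0.22 and edin by 2.04 ± 0.37. CecB, a cecropin named here because it completes the count, had 0.98 at 3 h and 1.89 at 6 h. AttD and Drsl4 were the members that did not pass, at -0.14 and 0.54 at 3 h and 0.30 and 0.22 at 6 h. Of 8 measured Bomanin and other Toll-induced peptide genes, out of 10 named on the array, 7 rose, again 7 when adjusted over the list alone. BomS4 rose by 2.18 ± 0.25 and BomBc3 by 1.49 ± 0.35, while IM33 stood at 0.37 and -0.11. The median of the antimicrobial peptide list was 0.98 at 3 h and 1.89 at 6 h and that of the Bomanin list 3.13 and 1.63, each above all of 10000 random lists matched on level (percentile 100). Between the uninfected arrays, 6 h against 3 h, the Bomanin list also stood at 1.50 (percentile 100). At 6 h these medians fell to 0.34 for the antimicrobial peptide list without the filter, which adds dim genes, and to 0.50 for the Bomanin list with the filter at the 75th percentile, their lowest percentiles over settings being 99.6 and 98.9.

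The lists of pathway components, proteases and serpins, and melanization genes held fewer calls. Among 15 Toll pathway components, 2 rose, SPE, the protease that activates the Toll ligand Spätzle, by 1.51 ± 0.23, and nec, a serpin that restrains the pathway, by 0.98 ± 0.24 (4 when adjusted over the list alone). The same 2 genes were the calls among 9 serine protease and serpin genes (3 adjusted over the list alone). Tl, the receptor, stood at 0.34 and 0.83 and psh, an upstream protease, at 0.39 and 1.30, neither past the test. Among 16 Imd pathway components only PGRP-SB1, a secreted peptidoglycan recognition protein, passed, with 2.27 ± 0.25 (1 adjusted over the list alone), and Rel, the transcription factor of the pathway, stood at -0.12 and 0.96. Of 13 melanization genes, yellow-f, a dopachrome-converting enzyme, rose by 1.60 ± 0.28 and Sp7, a protease of the phenoloxidase cascade, by 1.00 ± 0.20 (4 genes adjusted over the list alone). The prophenoloxidase genes PPO1 and PPO2 did not pass, with 0.12 and 0.11 at 3 h and -0.44 and -0.12 at 6 h.

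Blood cell markers divided by gene. Of 14 plasmatocyte markers, NimB3 rose by 1.54 ± 0.19 and NimB2 by 1.07 ± 0.20, both of which encode secreted proteins of the Nimrod family rather than surface receptors. The phagocytic receptor genes NimC1 and Sr-CI had -1.09 each at 3 h and -0.56 and -0.58 at 6 h, and neither passed over all genes, although 3 members passed as lower when adjusted over the list alone. None of the 7 lamellocyte markers, 3 crystal cell markers, 4 lectins, 7 JAK/STAT genes and 13 JNK and wound response genes passed limma. At an unadjusted p under 0.05 these lists held 0, 0, 1, 1 and 0 genes, the lectin being lectin-33A (-0.45 and -0.89) and the JAK/STAT target Tep4 (0.50 and 0.50). The lamellocyte genes mys, msn and Itgbn stood at -0.34, -0.01 and -0.19 at 3 h and at -0.05, 0.38 and -0.04 at 6 h.

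Lists of detoxification, metabolism and carrier protein genes held few calls. GstD5, a glutathione transferase, rose by 1.48 ± 0.24, the only call among 30 glutathione transferase genes (2 higher and 1 lower adjusted over the list alone). Of 54 cytochrome P450 genes, 3 fell, Cyp6a8 with a mean of -1.04, Cyp6a21 with -0.94 and Cyp6d5 with -0.84 (5 adjusted over the list alone). Of 12 redox enzymes, the peroxiredoxin gene Prx6c fell, with a mean of -1.24 (1 higher and 1 lower adjusted over the list alone). Obp99c and Obp99a, of 16 measured odorant binding protein genes, rose by 1.00 and 0.74 (3 adjusted over the list alone). Pepck1 and Obp99a were the calls among 13 insulin, FOXO and starvation genes (1 lower and 1 higher adjusted over the list alone). Bace, an aspartic protease of the gut, rose by 1.00, the 1 call among 20 other gut enzymes (3 higher and 3 lower adjusted over the list alone). Outside the lists, CG9928 rose by 2.37, CG2444 by 2.96, CG14567 by 2.21, CG2065 by 2.08 and the noncoding RNA gene lncRNA:CR33942 by 2.38, while CG34330 (-1.20), CG11425 (-1.19), ninaD, a scavenger receptor gene (-1.30), and Srr, which encodes serine racemase (-1.11), fell.

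In all, limma with time as a covariate called 80 probe sets higher and 35 lower at a Benjamini-Hochberg adjusted p under 0.05, and 112 of the 115 differed in the same direction at both times. The test itself favours such agreement, since it sets the mean of both times against the difference between them, so this count is no separate support. Higher calls were 69.6% of the total, against 88.9% with quantile normalization (48 higher and 6 lower), 89.5% for the values as deposited (51 and 6) and 80% with arrays centred on the filtered probe sets (68 and 17). It was 40.5% with the filter at the 75th percentile (70 and 103), 51.1% with a pseudocount of 1 (93 and 89) and 58.6% with robust eBayes (102 and 72), so the balance of calls depends on the processing. The fit had 1 residual degree of freedom and a prior of 24.5, so its errors were pooled almost entirely across probe sets. Without 1 array, and without the covariate, the counts were 8 and 0 (no control 3 h), 22 and 3 (no control 6 h), 52 and 12 (no infected 3 h) and 41 and 57 (no infected 6 h). Of the other settings that tested each gene, BomS2 passed in 4 of 10, BomBc2 in 3 of 9, BomBc3 in 1 of 8, edin in 4 of 9, nec in 3 of 9, Cyp6a8 in 5 of 10, Cyp6a21 in 4 of 10, Cyp6d5 in 3 of 10, Prx6c in 3 of 9, Bace in 4 of 9, Obp99a in 4 of 10, ninaD in 5 of 9, yellow-f in 6 of 9, and NimB2 and Alp10 in 6 of 10 each. Drs, Sp7 and Obp99c passed in 7 of 10 each, GstD5 in 7 of 9, BomT2 in 7 of 8, SPE, Pepck1, CG34330, CG11425 and Srr in 8 of 10 each, and PGRP-SB1, CG2444 and Alp9 in 9 of 10 each, against 10 of 10 for Mtk, DptB, NimB3, CG9928, CG2065 and lncRNA:CR33942. BomS4, BomS5, BomS6 and CG14567 passed in 9 of 9 each.

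**Figure D1:**
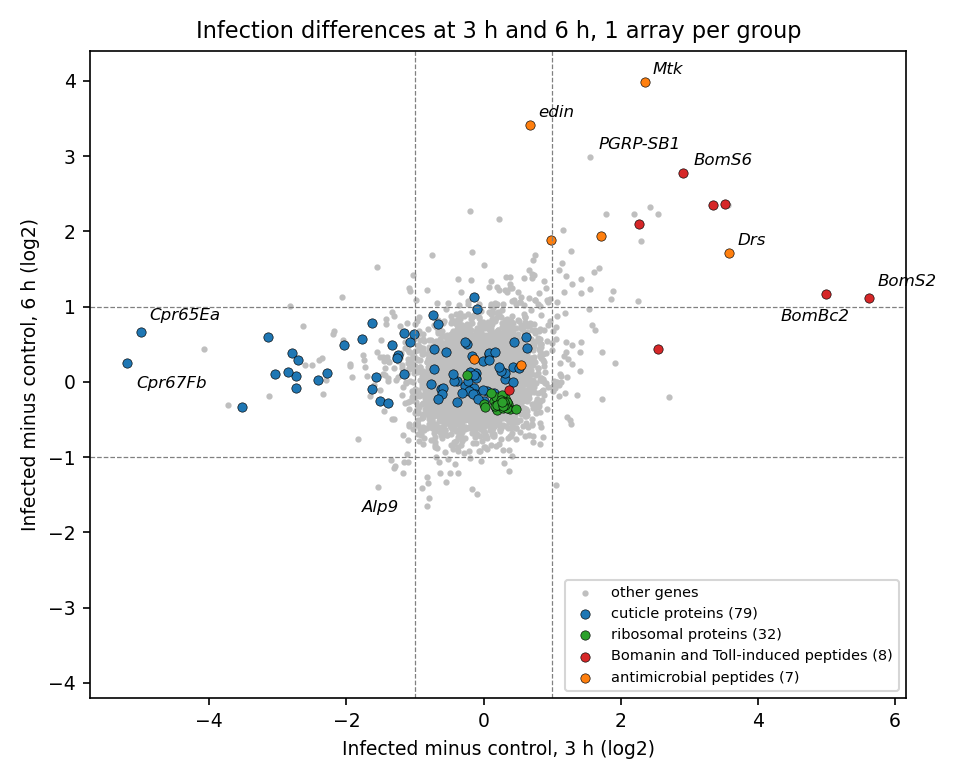
Each point is a gene, with its log2 difference between infected and control larvae at 3 h (horizontal axis) and 6 h (vertical axis); colours mark 4 gene lists with the number of measured genes, and dashed lines mark 2-fold. Bomanin and antimicrobial peptide genes such as BomS6 (2.91 and 2.78) and Mtk (2.35 and 3.98) lie high at both times, whereas cuticle genes such as Cpr67Fb (-5.19 and 0.25) lie low at 3 h alone.

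The comparison at 3 h concerned larvae frozen straight after 3 h with wasps. Among genes with a name here, Bomanin genes showed the highest values and genes of the cuticle the lowest. BomS2 signal was 61.4 in the control and 4214.9 in the infected sample, a difference of 5.62 (49.3-fold), Drs stood at 3.58, CG2444 at 3.56 and BomS5 at 3.52. In control 6 h, however, BomS2 signal was 2294.3, a difference of 4.69 from control 3 h, so this fold cannot be read as infection alone. BomBc2 and BomT2, with control signals under the pseudocount, stood at 5.0 and 3.34 or more and are not ranked here. Cpr67Fb and Cpr65Ea, which encode chitin-binding cuticle proteins, stood at -5.19 and -5.0, their signals being 3387 and 5199.4 in the control and 87.2 and 164.9 in the infected sample. CG14147 (-4.08), CG11584 (-3.73) and the Tweedle cuticle genes TwdlW (-3.52), TwdlD (-3.14) and TwdlS (-3.04) were among the next.

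Of 79 measured cuticle protein genes, 26 were over 2-fold lower at 3 h and 0 over 2-fold higher, and the list median of -0.39 lay below all of 10000 random lists (percentile 0). Over both times limma called 5 cuticle genes lower (15 lower and 1 higher adjusted over the list alone), Cpr67Fb, TwdlW, Cpr51A, TwdlB and TwdlM, the last pair named to complete the count after their values were seen. Cpr67Fb, Cpr51A and TwdlM were at 0.25, 0.08 and 0.02 at 6 h, so these calls rest on the 3 h arrays, and each of Cpr67Fb, TwdlW and Cpr51A passed in 2 of 10 other settings. Of those added over the list alone, Cpr65Ea and TwdlS stood at 0.66 and 0.11 at 6 h, so they too rest on 3 h, and TwdlL at -0.28. Counts adjusted over a list alone are not corrected for the number of lists. The ratio of 3' to 5' signal, a sign of RNA quality, was highest in infected 3 h for actin, eIF-4a, Act5C and GAPDH (4.24 for Act5C against 2.63 in control 3 h). For GAPDH the margin was small, with 1.64 in control 3 h and 2.12 to 2.14 in the other arrays. The median of 32 cytosolic ribosomal protein genes was 0.27 (percentile 100; 0.068 and percentile 97.25 with quantile normalization), and on the same scale the bioD and cre hybridization controls, which are added in equal amount to each array, stood at 0.17. RpL27 stood at 0.20 and RpL34a at 0.00. None of the 32 passed limma over both times, and 0 did at an unadjusted p under 0.05.

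The 16 odorant binding protein genes had a median of 0.60 at 3 h (percentile 100), with Obp28a at 0.99 and Obp99c at 0.92. Of 7 heat shock genes, Hsp68 stood at 1.02, Hsp26 at 0.77 and Hsp27 at 0.65, and the list median was 0.14 (percentile 98.6); none passed limma over both times, 1 at an unadjusted p under 0.05. Cytochrome P450 genes had a median of -0.26 (percentile 0.58), insulin, FOXO and starvation genes -0.32 (percentile 3.72), and melanization genes 0.23 (percentile 99.9). Toll pathway components had a median of 0.17 (percentile 99.98), serine protease and serpin genes 0.14 (percentile 99.3), Imd components -0.13 (percentile 63.0) and plasmatocyte markers -0.24 (percentile 16.7). Lamellocyte, crystal cell, lectin, JAK/STAT and JNK lists had medians of -0.09, 0.11, -0.08, 0.00 and -0.17, at percentiles 75.8, 94.8, 53.6, 85.1 and 39.3. The glycolysis, lipid synthesis, gut protease, other gut enzyme and salivary glue lists stood at -0.12, -0.12, -0.03, -0.23 and 0.11. With quantile normalization gut proteases stood at -0.11 (percentile 1.19), and with the filter at the 75th percentile other gut enzymes stood at -0.50 (percentile 0.11). The serine protease and serpin, Imd, lamellocyte, lectin, JAK/STAT, JNK, glycolysis, lipid synthesis, gut protease and salivary glue medians at 3 h crossed 0 in other settings. Of 18 glycolysis and trehalose genes, 0 passed limma over both times, 1 at an unadjusted p under 0.05 and 1 adjusted over the list alone, with Pdk, a kinase of pyruvate dehydrogenase, at -0.88.

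Between the uninfected arrays, time included, 104 probe sets were over 2-fold higher and 202 over 2-fold lower at 6 h than 3 h. With infection at 3 h, 105 probe sets were over 2-fold higher and 170 over 2-fold lower, with no test. Counts of this size do not by themselves show a response to infection. Quantile normalization turned the balance at 3 h of infection to 128 higher and 126 lower, the deposited values to 149 and 112 and centring on the filtered probe sets to 149 and 111. Under the main scaling the median of all kept probe sets was -0.13 at 3 h, against 0.02 as deposited.

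**Figure D2:**
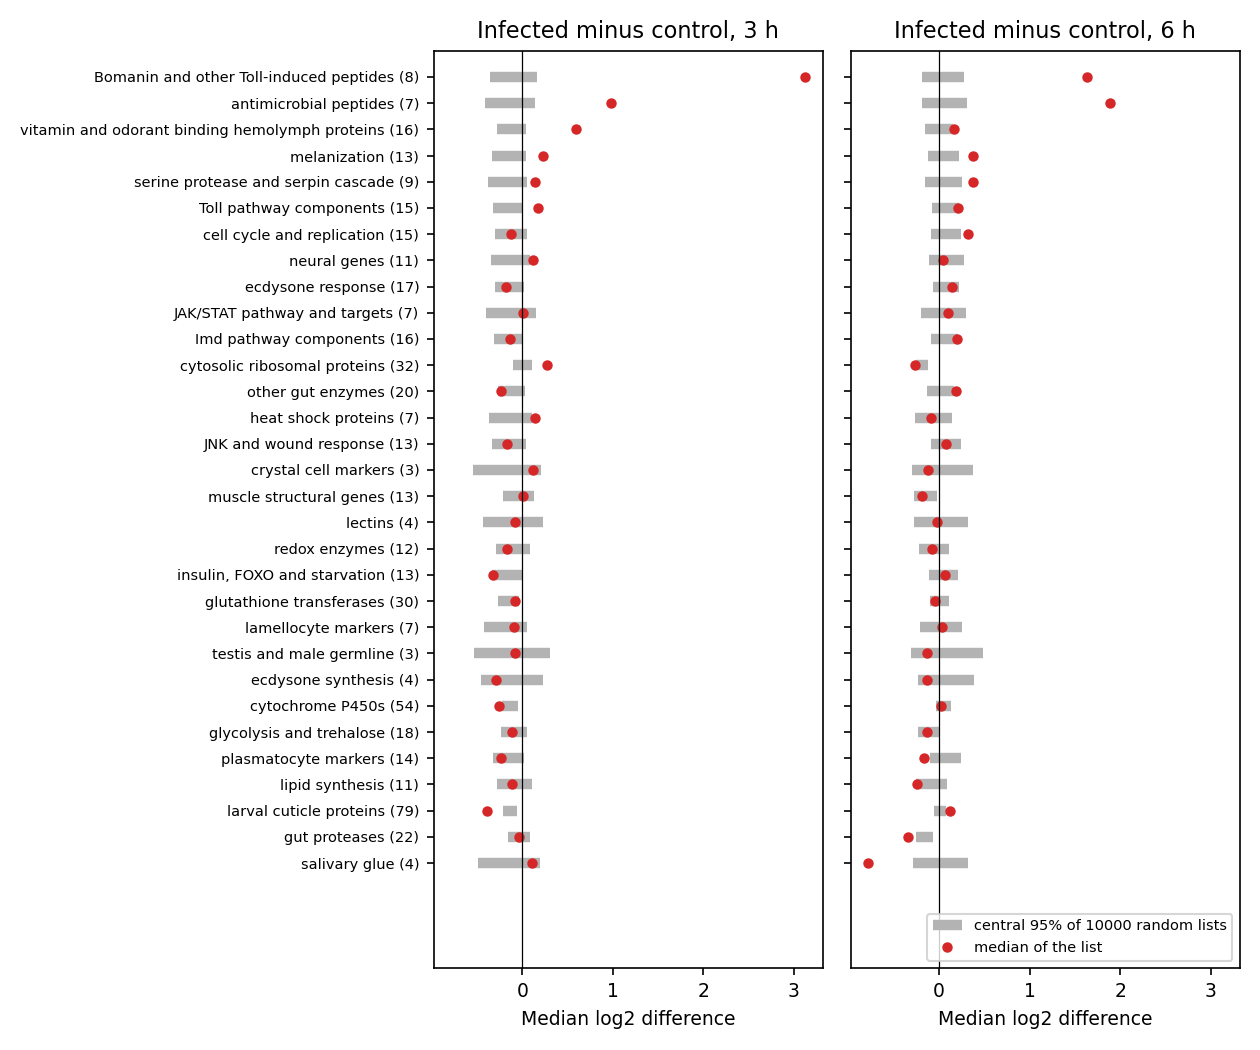
Red points give the median log2 difference between infected and control larvae of each gene list at 3 h (left) and 6 h (right), with the number of measured genes in brackets, and grey bars the central 95% of 10000 random lists matched on level. The Bomanin list (3.13 and 1.63) and the antimicrobial peptide list (0.98 and 1.89) lie far above the bars at both times, and the cuticle list lies below its bar at 3 h (-0.39).

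The comparison at 6 h concerned larvae that had spent 6 h with wasps. Among genes with a name here, immune peptide genes had the highest values, Mtk at 3.98 (15.8-fold, signal 400.3 in the control and 6607.3 in the infected sample) and edin at 3.41 (10.7-fold). PGRP-SB1 stood at 2.99, BomS6 at 2.78, BomS5 at 2.36, BomT2 at 2.35 and BomS4 at 2.10. The lowest named genes were nearer 0 than at 3 h and included Prx6c at -1.66, CG14422 at -1.55, Rca1, which regulates mitotic cyclins, at -1.48, Alp9 at -1.40 and Cyp6a21 at -1.34.

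Among the lists at 6 h, melanization genes had a median of 0.38 (percentile 99.97; 93.7 with the filter at the 75th percentile) and serine protease and serpin genes 0.37 (percentile 99.8). Toll and Imd pathway components stood at 0.21 (percentile 97.1) and 0.20 (percentile 97.1), with Tl at 0.83 and Rel at 0.96. Plasmatocyte markers had a median of -0.17 (percentile 0.32), with NimC1 at -0.56 beside NimB2 at 1.48. Lamellocyte, crystal cell, lectin, JAK/STAT and JNK medians were 0.03, -0.12, -0.03, 0.10 and 0.07, at percentiles 55.9, 16.8, 45.5, 67.3 and 51.6, and all of these but the crystal cell median crossed 0 in other settings. The 15 cell cycle genes had a median of 0.32 (percentile 99.7; -0.13 at 3 h, where it crossed 0 in other settings), with CycE at 0.44 and Mcm2 at 0.32, and 0 passed limma over both times, also at an unadjusted p under 0.05.

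Digestive gene lists had medians of opposite sign at 6 h, a difference not tested. The 20 other gut enzymes, largely maltases and mannosidases, had a median of 0.19 (percentile 98.9), with Amyrel at 1.08 and Bace at 1.07. This list came inside the central 95% with quantile normalization (percentile 96.5), without the filter (96.9) and with the filter at the 75th percentile (median -0.11, percentile 19.3). The 22 gut proteases, trypsin and chymotrypsin-like enzymes of the midgut, had a median of -0.34 (percentile 0.01, central 95% of random lists -0.26 to -0.07). It was -0.13 with quantile normalization, and the percentile was 0.04 or lower in every setting. The main median lay near the -0.33 of the bioD and cre hybridization controls, with Jon66Cii at -0.61 and kappaTry at -0.51. The control 6 h array it rests on also had this list 0.14 above control 3 h (percentile 99.85). None of the 22 passed limma over both times, 5 were lower at an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone. The 4 measured salivary glue list genes had a median of -0.78 (percentile 0), with ng1, ng2 and ng3 at -0.73, -0.87 and -0.83 and ng4 at 0.27; none passed limma, 2 at an unadjusted p under 0.05, and 1 when adjusted over the list alone. Lipid synthesis genes stood at -0.25 (percentile 3.68), FASN1, the fatty acid synthase, at -0.37, with 0 calls by limma and 1 at an unadjusted p under 0.05. Ribosomal protein genes had a median of -0.27 (percentile 1.03; -0.0017 and percentile 54.5 with quantile normalization) where the bioD and cre hybridization controls stood at -0.33. The cuticle list median was 0.12 (percentile 99.9) with 0 genes over 2-fold lower, the odorant binding list 0.16 (percentile 97.7; 0.030 and percentile 73.1 without the filter), and the P450 list 0.02 and the glycolysis list -0.13, which both crossed 0 in other settings.

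Beside 104 higher and 202 lower between the uninfected arrays, infection at 6 h had 126 probe sets over 2-fold higher and 32 over 2-fold lower. Centring on the filtered probe sets gave 91 and 45 for infection at 6 h. Both times shared 43 probe sets over 2-fold higher and 8 over 2-fold lower, where independent lists of these sizes would share 1.41 and 0.58, and Pearson's correlation of the differences at the 2 times over all kept probe sets was 0.19 (Spearman 0.01; 0.04 for Pearson without the filter). The genes lower at both times included Alp9 (-1.53 and -1.40), CG11425 (-1.17 and -1.22), CG34330 (-1.29 and -1.11), Pepck1 (-1.31 and -1.14), Alp10 (-1.11 and -1.07) and Srr (-1.16 and -1.06).

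**Figure D3:**
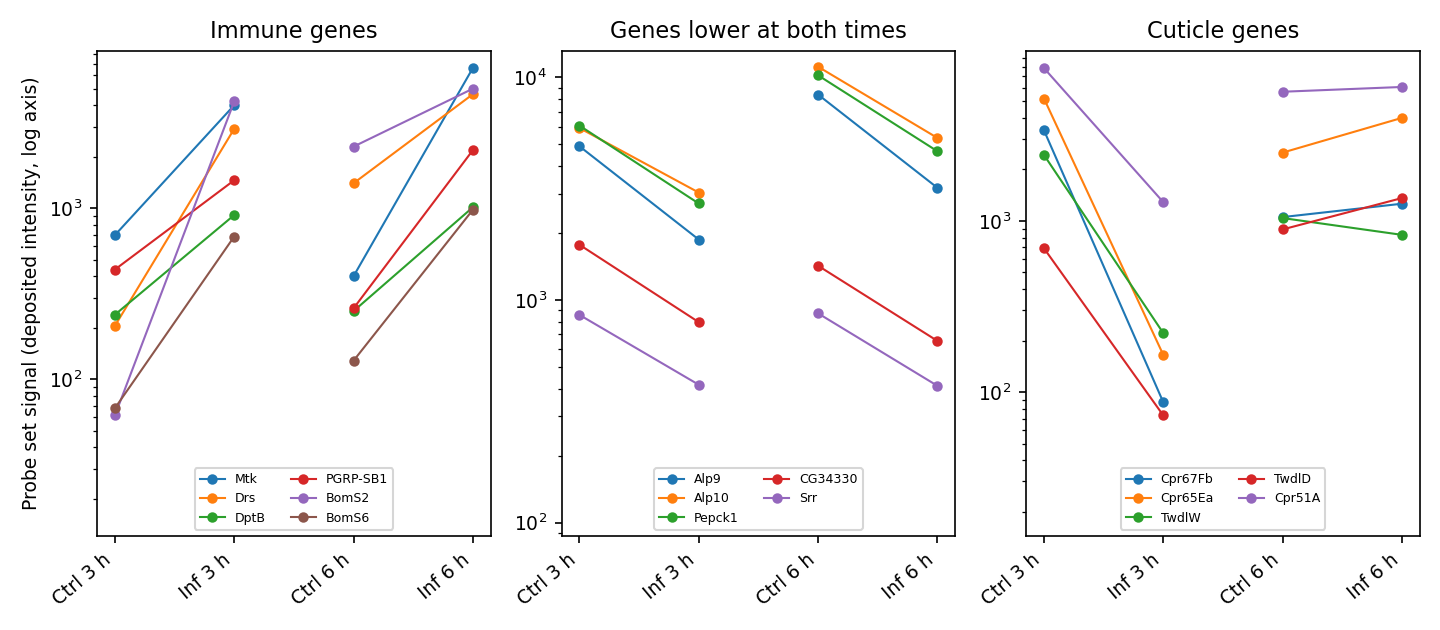
Deposited signal of named genes on a logarithmic axis in the 4 arrays, 1 array per point, with lines joining the control and infected arrays of each time. The immune genes shown were higher in the infected array at both times, Alp9, Alp10, Pepck1, CG34330 and Srr lower at both, and cuticle genes such as Cpr67Fb (3387 in control 3 h, 87.2 in infected 3 h) lower at 3 h.

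The arrays also allowed control larvae at 6 h to be set against control larvae at 3 h. Bomanin genes differed between the uninfected samples, BomS2 by 4.69 (signal 61.4 at 3 h and 2294.3 at 6 h) and BomBc2 by at least 4.50 (signal 3.5 and 492.1), with a list median of 1.50 (percentile 100), and Drs by 2.47. The antimicrobial peptide list as a whole stood at -0.14 (percentile 73.6). CG14564 (3.94), CG42819 (2.92), CG16772 (2.91) and CG14573 (2.77) were also among the highest at 6 h. CG7406 (-3.35), CG31437 (-3.23), the cuticle gene Cpr47Ed (-3.21), spz6, a Spätzle-family ligand (-2.46), and ImpE2, an ecdysone-inducible gene of imaginal discs (-2.34), were among the lowest. Neural genes had a median of 0.41 (percentile 100), ribosomal protein genes 0.23 (percentile 100; 75.5 with quantile normalization), cell cycle genes -0.46 (percentile 1.06; 9.22 with the filter at the 75th percentile) and salivary glue genes -0.81 (percentile 0.06; 89.5 without the filter). Cuticle genes stood at 0.06 (percentile 100), odorant binding genes at 0.12 (percentile 99.9) and muscle genes at 0.13 (percentile 98.8). Melanization genes stood at 0.14 (percentile 99.94, or 97.1 with the filter at the 75th percentile). Gut proteases also stood at 0.14 (percentile 99.85, or 95.5 with quantile normalization). The Toll, JNK, P450 and glycolysis lists lay above the central 95% too, with medians given further below.

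Over both infection states limma called 134 probe sets higher and 115 lower at 6 h. CG14564 rose by 3.17, CG42819 by 2.97 and BomBc2 by a fitted mean of 2.58 (at least 4.50 between controls and 0.66 between infected larvae). CG7406 (-2.53), Jhbp4, of the juvenile hormone binding protein family (-2.07), CG14422 (-1.98) and ng2 (-1.62) fell. Of 79 cuticle genes, 19 rose and 4 fell at 6 h, the 19 by a median of 0.96 between controls and 1.56 between infected larvae, and TwdlD, among them by 2.02, by 0.15 and 3.88, so that its call rests on the infected arrays. Between controls alone, 8 cuticle genes were over 2-fold higher and 13 over 2-fold lower at 6 h. Higher calls were 53.8% of the total, against 71.2% with quantile normalization (94 and 38), 73.4% as deposited (102 and 37) and 65.4% with centring on the filtered probe sets (134 and 71). It was 46.2% with the filter at the 75th percentile (140 and 163), 47.0% with a pseudocount of 1 (157 and 177) and 45.2% with robust eBayes (159 and 193). Between the controls the over 2-fold counts of 104 higher and 202 lower became 158 and 126 with quantile normalization, 182 and 100 as deposited and 205 and 92 with centring on the filtered probe sets. Poly-A spike control probe sets differed 12.6-fold between the 3 h and 6 h control arrays and 19.9-fold between the infected ones, so time cannot be told apart from the preparation of the arrays. Without 1 array, and without the covariate, the time counts were 131 and 45 (no control 3 h), 82 and 99 (no infected 3 h), 0 and 0 (no control 6 h) and 0 and 0 (no infected 6 h).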

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

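All tests that weigh explanations here were chosen after the results were seen, and no difference between the responses at 3 h and 6 h was tested, since each response rests on 1 array per group.

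Infected larvae were higher at both times for 6 of 7 measured antimicrobial peptide genes and 7 of 8 Bomanin list genes, with 15 measured genes in all. The others were AttD, at -0.14 at 3 h, and IM33, at -0.11 at 6 h. Scaling or brightness of the arrays is argued against by the lowest median of the genes of both lists over both times and 8 scaling, pseudocount and filter settings, 0.98 over 23 genes without the filter, against a bound of 0.6 taken from the hybridization controls; the antimicrobial list alone fell to 0.34 and the Bomanin list to 0.50 at 6 h, where those controls moved by -0.33. A low level in the control 3 h sample as the whole cause at 3 h stays open. Infected 3 h larvae were above control 6 h larvae in all 15 genes, with a median of 1.55 (interquartile range 0.72 to 1.97). That comparison cannot decide, because it crosses the times, which cannot be told apart from the preparation of the arrays. It also counts AttD, at -0.14 against its own control at 3 h, because AttD differed by -2.09 between control 6 h and control 3 h. BomS2 and BomBc2 were 4.69 and at least 4.50 higher in control 6 h than in control 3 h. A wound or microbes carried in by the sting remain open beside the parasite itself, because no stung larvae without a parasite egg are analysed here, and the JNK and wound list, at percentile 51.6 of random lists at 6 h, does not decide it. A response to the parasite itself stays a hypothesis.

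Cuticle protein genes opposed between times, with a list median of -0.39 at 3 h and 0.12 at 6 h. Loss of cuticle or epidermis from the infected 3 h sample would lower these genes together and is argued against by the share over 2-fold lower, 32.9% of 79 genes, with 19 genes above 0. A difference in developmental stage between samples stays open: the 34 cuticle genes over 2-fold lower in infected 3 h than infected 6 h larvae had a median absolute difference of 0.77 between the uninfected arrays, but 20 went the same way there and 14 the opposite way, and random lists, not picked for change, give no yardstick. An effect of infection limited to 3 h stays open too, since the 26 genes over 2-fold lower at 3 h had a median of 0.27 at 6 h, which neither needs nor forbids one. Set against the mean of the 6 h arrays these 26 genes stood at -1.64 in infected 3 h and at 0.57 in control 3 h.

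Cytosolic ribosomal protein genes opposed between times as well, with medians of 0.27 at 3 h and -0.27 at 6 h over 32 genes. Array brightness at high signal is a candidate explanation, since the bioD and cre hybridization controls moved alike, by 0.17 (range 0.09 to 0.32) at 3 h and -0.33 (range -0.47 to -0.25) at 6 h on the same scale, and quantile normalization left list medians of 0.068 and -0.0017. An effect of infection on these transcripts cannot be told apart from it, because what remains after subtracting the controls' median is 0.10 at 3 h and 0.06 at 6 h.

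Poly-A control transcripts, spiked into RNA before labelling and used in no comparison, gave signals 12.6-fold higher in control 3 h than control 6 h and 19.9-fold higher in infected 3 h than infected 6 h (24 probe sets, median signals 471, 597, 31.2 and 19.6 in control 3 h, infected 3 h, control 6 h and infected 6 h). Among all kept probe sets, 9 were over 2-fold in opposite directions at the 2 times, 3 higher and then lower and 6 lower and then higher (0.36 and 2.28 from independent lists), a difference not tested. Among the 5 genes each way with the largest difference between responses, those opposed in sign at the 2 times, likewise not tested, had a 6 h minus 3 h response of 5.66 for Cpr65Ea, 5.44 for Cpr67Fb, 4.51 for CG14147, 3.83 for CG13048, 3.73 for TwdlD, -2.91 for CG13438 and -2.43 for CG16772.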

How the results depend on the processing

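Every alternative named here was planned except centring on the filtered probe sets, which was added after the data were seen. For infection over both times, 11 probe sets passed limma in all 10 settings that keep the time covariate, namely Mtk, CG2444, lncRNA:CR33942, CG9928, CG2065, Srg1, DptB, NimB3, Idgf1 and 1 unnamed probe set, all higher, and Alp9, lower. BomS4, BomS5, BomS6 and CG14567 were not tested in every setting, and passed in all 9 other settings that tested them. Against 80 higher and 35 lower, quantile normalization gave 48 and 6, the values as deposited 51 and 6, no filter 16 and 1, and no covariate 19 and 0. The lower count alone moved by more than 1.5 times to 103 with the filter at the 75th percentile, 89 with a pseudocount of 1, 18 with 64, 17 with centring on the filtered probe sets, 14 without the trend and 72 with robust eBayes. Leaving out 1 array, without the covariate and with the lone array of a group taken to vary like the other group, gave 8 to 52 higher and 0 to 57 lower.

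For time, against 134 higher and 115 lower at 6 h, no filter gave 35 and 10 and no covariate 32 and 11. The lower count became 38 with quantile normalization, 37 as deposited, 177 with a pseudocount of 1, 71 with centring on the filtered probe sets, 74 without the trend and 193 with robust eBayes. Leaving out 1 array, again without the covariate, so that both choices changed at once, gave 0 to 131 higher and 0 to 99 lower.

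For over 2-fold differences, no filter gave 794 higher and 806 lower at 3 h, 813 and 825 at 6 h, 109 and 76 at both times and 778 and 838 between controls, and a correlation between the responses of 0.039 in place of 0.19. With the filter at the 75th percentile, which tests fewer probe sets, these counts were 39 and 91, 51 and 14, 21 higher at both times, and 50 and 81. A pseudocount of 64 gave 69 and 103 at 3 h, 82 and 18 at 6 h, 5 lower at both times and 94 lower between controls. A 1.5-fold threshold gave 358 and 735, 452 and 213, 106 and 53 at both times, and 340 and 1171 between controls, and a 3-fold threshold 41 and 44, 35 and 3, 20 and 0, and 53 and 46. Scaling moved the lower count at 3 h to 112 as deposited and 111 with centring on the filtered probe sets, and the counts between controls to 158 and 126 with quantile normalization, 182 and 100 as deposited and 205 and 92 with centring on the filtered probe sets. Beyond the direct effect of filters, thresholds and fewer arrays, the cause was not tested.

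List medians changed sign in 95 of 738 values under alternatives, 43 for controls at 6 h against 3 h (16 lists), 35 at 3 h of infection (15 lists) and 17 at 6 h (11 lists). Those outside the central 95% of random lists that did so were, for controls at 6 h against 3 h, JNK and wound genes (-0.02), Toll components (-0.01) and P450 genes (-0.10). Quantile normalization gave 0.23, 0.22 and 0.068, the values as deposited 0.19, 0.19 and 0.11, centring on the filtered probe sets 0.22, 0.23 and 0.14, a pseudocount of 64 gave 0.039 and 0.047 for JNK and Toll, and the mean of a gene's probe sets 0.0028 for Toll. Also between controls, glycolysis genes became -0.012 with a pseudocount of 1 (0.03 before), and salivary glue genes 0.094 without the filter (-0.81). At 6 h of infection, other gut enzymes became -0.11 with the filter at the 75th percentile (0.19), and at 3 h the serine protease and serpin genes -0.017 without the filter (0.14). Lists that came inside the central 95% without a change of sign included ribosomal protein genes with quantile normalization (0.068 at 3 h, -0.0017 at 6 h and 0.017 between controls), melanization genes at 6 h with the filter at the 75th percentile (0.19), odorant binding genes at 6 h without the filter (0.030), and cell cycle genes between controls (percentile 9.22) and neural genes at 3 h (0.081) with the filter at the 75th percentile. Others came outside it. With the filter at the 75th percentile these were other gut enzymes at 3 h and ecdysone response genes at 6 h and between controls. Gut proteases did so at 3 h with quantile normalization, and Toll and Imd components at 6 h with a pseudocount of 1 (percentiles 97.9 and 97.8). Ecdysone response genes also did so at 6 h with the mean of a gene's probe sets. Of the other values under alternatives, for lists and named genes, 6627 kept direction and side, 331 changed sign without being past their threshold, 177 were no longer past their threshold, 43 came past it and 109 moved. The fit with time as a term compares infected with control within each time, and no covariate is the same fit without it. Signal over background limits dim genes: the median signal was 65.6 to 78.8 against a pseudocount of 16.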

Other observations

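No further explanation is tested here, and the genes named outside the lists were chosen after their values were seen.

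Further genes outside the lists rose with infection over both times by limma. Srg1 stood at 1.78 and 2.23 at 3 h and 6 h, Idgf1, a chitinase-like growth factor gene, at 1.55 and 1.24, and Listericin, an antibacterial protein gene, at 1.18 and 1.20. The highest differences at both times among probe sets without a gene name here were 4.92 and 4.15 (1627271_at) and 4.26 and 3.22 (1625698_at), and 1637115_at fell, with -1.07 and -1.69.

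Hormone, tissue and germline lists gave no call by limma over both times. The 17 ecdysone response genes had medians of -0.18 at 3 h and 0.14 at 6 h (percentiles 34.1 and 83.8, with 1 gene at an unadjusted p under 0.05), with ImpE1 at 1.03 and 0.01 and ImpL1 at 0.29 and 1.03. Their 6 h median depended on the processing. It was 0.63 (percentile 100, 6 genes) with the filter at the 75th percentile and 0.30 (percentile 99.7) with the mean of a gene's probe sets. The 4 measured ecdysone synthesis genes stood at -0.29 and -0.14, 13 muscle genes at 0.00 and -0.19, 11 neural genes at 0.11 and 0.04 and 3 testis genes at -0.08 and -0.13, with 0 genes of these lists at an unadjusted p under 0.05. The troponin gene up stood at 0.89 and -0.18, spok at -0.30 and 0.05, and the synaptic gene Snap25 at 0.56 and -0.01. Redox enzymes had medians of -0.17 and -0.07, glutathione transferases -0.08 and -0.05, heat shock genes -0.09 at 6 h, and insulin, FOXO and starvation genes 0.06 at 6 h. The ecdysone response, muscle, testis and glutathione transferase medians at 3 h and the ecdysone synthesis, neural, redox and insulin medians at 6 h crossed 0 in other settings.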
